A study of Mus musculus with 4 samples.

How the data were processed

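RNA from mouse kidney was measured on 4 one-colour Agilent expression arrays, 1 for each combination of genotype and operation. Per the labels, the mice were C57BL/6 wild type or lacked Nlrc5, were 8 weeks old, and had a sham operation or 30 min of ischemia of both kidneys followed by reperfusion. The labels give the reperfusion time as 48 h in the sample titles and the series design and as 24 h in the sample descriptions, and this conflict was not resolved. Groups were taken from the labels, and each group held 1 array.

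The deposited scanner files hold spot intensity values made by Agilent Feature Extraction, version 10.7.3.1 per the file headers and 9.1 per the submitters' processing notes. The processed intensity of each spot had been background-subtracted and detrended within its array, per the file headers, and had not been scaled between arrays. A deposited table of the same arrays holds log2 values made by the authors, with the normalization between arrays not given in the sources used here. Its columns had medians of 5.91 to 5.93 and rank correlations above 0.9999 with the scanner intensities, and no centring of genes was seen. It served as an alternative. Probe coordinates in the files are those of the mm9 mouse genome build.

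Each array carried 45018 spots, of which 43379 were not controls and represented 41174 probes. Control spots and spots with either of 2 outlier flags were left out, and spots of a probe were averaged, which left 41142 probes. Values are log2 of the processed intensity minus the 75th percentile of each array. Probes were named through RefSeq accessions (27649 probes), symbols (5584) or synonyms (471) of the GRCm38.p6 gene table. A further 1154 probes kept the name in the file, and 6284 stayed unnamed. The probe with the highest mean signal represented each of 21113 genes. A gene was tested by limma where its probe was well above background on at least 2 arrays (16555 genes).

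Where a probe was not well above background on an array, its value there was taken as the higher of its own signal and the lowest signal among probes well above background on that array, and the difference is given as "at least". Differences between 2 arrays were counted at 2-fold, among genes above background on either array. Differences between the injury responses were counted among 14949 genes above background on all 4 arrays. With 1 array per group these counts have no replicate check and no p-value.

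The limma fits (version 3.58.1, R 4.3.3) had genotype and treatment as additive terms, which left 1 residual degree of freedom, and p-values were adjusted by the Benjamini-Hochberg method. In these fits the spread comes from how far the injury response differed between the genotypes, so a true difference in response counts as error. Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. For differences between 2 arrays, the median of a list was placed among 10000 random lists of the same size matched on expression in 20 bins. This percentile describes these arrays only. Lists of kidney genes higher in male or female mice and a further list of fat markers were written later, after the sex-chromosome genes or the first fat genes had been seen.

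The genes named in the text follow a rule fixed before the data were examined. For injury, it took the 12 genes with the largest difference each way, by the smaller of the changes in the 2 genotypes. For genotype, it took the 10 largest differences each way within each treatment and the 4 largest bounds, and the 8 largest each way over both treatments. For the difference between responses it took 8 each way, and for each list the 3 largest members. Nlrc5 and Ceacam1 are always given, and predicted genes were skipped. The text gives a selection of these genes, and 2 of them are not reported here.

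The procedures were tested on simulated arrays with the fitted prior (2.52 degrees of freedom, SD 0.30). Over 5 simulations of 16555 genes, the injury fit recovered 0 of 250 genes changed by 1 on the log2 scale, 0 of 250 changed by 2, 2 of 250 changed by 4 and 66 of 250 changed by 6, with 4 false calls. The genotype fit recovered 0, 0, 72 and 139 of 250 at those sizes, with 18 false calls. Both fits drew variances from the same prior and compared 2 arrays with 2. The gap between them thus comes from the random draws and does not make the genotype fit more sensitive. For the injury comparison, among 50 simulated lists of 30 genes shifted by 1, camera found 50 at the preset correlation and 0 at the estimated correlation at an unadjusted p under 0.05. Among 50 lists with no shift it found 2 and 0. The percentile lay outside 2.5 to 97.5 for 50 shifted and 4 unshifted lists. Genes were simulated independently of each other, so these counts do not cover lists whose members vary together.

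Alternatives covered background correction (limma normexp, offset 50), scaling, filters, probe choice, covariates, the variance prior, thresholds, each array left out, and random lists without matching. Both wild type arrays lay on slide 1 and both arrays labelled knockout on slide 2, with the same split by scan, so slide and genotype cannot be told apart and the slide was not fitted apart from genotype. Figures were drawn with matplotlib 3.10.9.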

Results

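Gene expression was measured in kidneys of wild type mice and of mice lacking Nlrc5, a regulator of MHC class I genes in the NOD-like receptor family, after a sham operation or ischemia and reperfusion. Each of the 4 groups had 1 array. The 75th percentile of the processed signal was 456.2 in wild type sham, 465.4 in knockout sham, 181.7 in wild type injured and 362.2 in knockout injured. Between 67.2% and 74.6% of probes were well above background. Spots of the same probe gave an SD of 0.18 for a log2 difference between 2 arrays, which is technical noise only and leaves out differences between animals.

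Nlrc5 was higher by 0.32 on the array labelled knockout in sham kidneys and stood at -0.28 in injured kidneys. Its single probe (A_52_P382107, chromosome 8, 97044928 to 97044987, mm9) read -4.05 in wild type sham and -3.73 in knockout sham. It read -3.30 in wild type injured and -3.58 in knockout injured, well above background on all 4 arrays. With normexp background correction fitted without flagged spots, an alternative chosen after seeing the data, it differed by -0.66 between the injured arrays. The sources used here do not give the deleted part of the gene, so a probe outside it would check nothing. Genotypes are therefore named below as the arrays are labelled. Ceacam1, the adhesion receptor named in the title of the series, was higher on the arrays labelled knockout by its brightest probe, by 0.83 in sham and 1.69 in injured kidneys. That probe read 3.57, 4.40, 2.34 and 4.03 in wild type sham, knockout sham, wild type injured and knockout injured. A second Ceacam1 probe read -2.69, -2.21, -3.05 and -2.65 on the same arrays. The remaining Ceacam1 probe read -3.79, -3.76, -4.58 and -4.77, was not well above background in wild type injured, and was not higher in knockout injured.

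The sex-chromosome genes set the knockout sham array apart from the other 3. Xist, expressed from the inactive X chromosome of females, had a signal of 17116 there and was not well above background on the others. Ddx3y, Eif2s3y, Kdm5d and Uty, all on the Y chromosome, were not well above background on that array and were so on the other 3. The knockout sham sample thus had a female pattern and the others a male pattern, and each comparison with knockout sham also compares sexes.

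**Figure D1:**
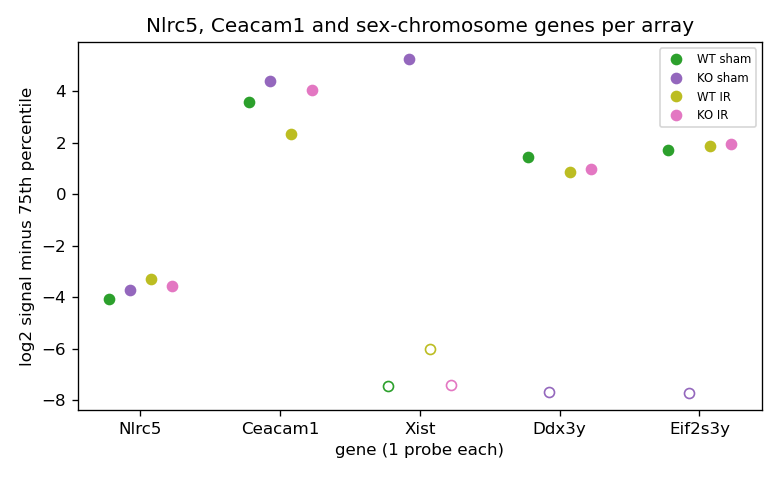
Log2 signal minus the 75th percentile for 1 probe of each gene on each of the 4 arrays, with open points for probes not well above background. Nlrc5 lay between -4.05 and -3.30 on the 4 arrays, and Xist was above background in knockout sham alone.

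The comparison of injured with sham kidneys over both genotypes asks which genes follow ischemia and reperfusion. Krt20, a keratin, was higher after injury by 7.64 in wild type and 4.94 in knockout. The neutrophil chemokine Cxcl1 was higher by 4.46 and 3.92, the protease inhibitor Timp1 by 4.17 and 3.50, and the centromere protein Cenph by 3.80 and 3.67. The renin gene Ren1 was lower, at -3.10 in wild type and -2.51 in knockout by its brightest probe. Its other probe stood at -1.83 and -2.37. The probe named for Ren2 stood at -2.70 and -2.78, and whether it reads a transcript apart from Ren1 was not tested. Cyp26b1, which degrades retinoic acid, stood at -3.52 and -2.71. The amino acid transporter gene Slc7a12 stood at -5.38 and -2.88. It is a member of the list of kidney genes higher in female mice. It read 2.72 in wild type sham, 5.78 in knockout sham and 2.90 in knockout injured. Its fall in knockout thus rests on the sham array of female pattern. The cell cycle gene E2f8 was higher by 3.71 in wild type and, as it was not above background in knockout sham, by at least 3.42 in knockout. With normexp fitted without flagged spots Cenph stood at 2.47 and 2.10 and E2f8 at 1.78 and 1.45.

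Of 16555 genes tested by limma, 0 passed an adjusted p of 0.05 for injury, and the smallest adjusted p was 0.4. At an unadjusted p under 0.05, 858 genes were higher and 1016 lower. The count depended on the background correction: with normexp fitted without flagged spots limma called 730 genes. A fit without the knockout injured array, which also had to leave out genotype as a term, called 702. These p-values measure only the spread between these samples, and the number of arrays limits the precision. By size alone, 422 genes were higher and 313 lower by at least 2-fold in both genotypes. These counts used each probe's own signal, also where it was not well above background, and not the bounds. Some of these genes were less than 2-fold apart as bounds, such as Tmprss6 at -0.71 in wild type.

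Cell cycle genes had a median of 2.68 over both genotypes and 26 members. Adjusted over the list alone, 23 of the 26 rose, against 0 over all genes. Ccnb2 and Top2a were higher by 4.03 and 3.98 in knockout, and Ccne1 and Rrm2 by 3.78 and 3.67 in wild type. Among 30 tubular injury and repair genes the median was 1.92, and 15 rose adjusted over the list alone, against 0 over all genes. Proximal tubule genes had a median of -1.19 over 39 members, oxidative phosphorylation genes -0.64 over 23, and endothelial genes -0.73 over 14. Markers of other tissues were lower in the same comparison, with medians of -4.02 over 3 erythroid genes (camera adjusted p = 9.24e-03) and -2.71 over 5 urothelium genes (camera adjusted p = 0.0184), and adjusted p = 0.884 for each with an estimated correlation. The camera adjusted p at the preset correlation was 1.55e-17 for cell cycle, 1.75e-12 for tubular injury, 4.47e-05 for proximal tubule, 1.44e-06 for oxidative phosphorylation and 1.97e-04 for endothelial genes. Each of these calls was lost with an estimated correlation, where the adjusted p was 0.884, a setting that found 0 of 50 shifted lists in simulation. The simulated genes varied independently, while the estimated correlation was 0.63 for tubular injury and 0.71 for proximal tubule genes. The simulation therefore cannot decide between the 2 settings for lists whose members vary together.

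In wild type kidneys alone, injury went with higher tubular injury genes and lower proximal tubule genes. The tubular injury median was 2.77, with 26 of 30 genes higher by at least 2-fold, among them Krt20 at 7.64 and the neutrophil gelatinase-associated lipocalin gene Lcn2 at 6.54. Of 39 proximal tubule genes 31 were lower by at least 2-fold, with a median of -2.27. The phosphate transporter gene Slc34a3 stood at -7.28. Immediate early genes had a median of 2.21, with Fosl1 at 4.52 (2.87 with normexp fitted without flagged spots) and Egr1 at 3.29. Adipocyte genes had a median of -2.92, podocyte genes -1.46 and urothelium genes of the renal pelvis -3.41, and with normexp fitted without flagged spots -1.77, -0.67 and -0.97. The adipocyte and urothelium genes also stood at medians of -4.58 and -1.57 in knockout sham relative to wild type sham. A high level in wild type sham thus enters their fall. In all, 2403 genes were higher and 2099 lower by at least 2-fold, of 16660, a balance that turned with median scaling (2100 and 2461) and in the authors' value table (2124 and 2275).

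On the arrays labelled knockout, cell cycle genes had a median of 2.62, with 24 of 26 higher by at least 2-fold. Tubular injury genes had a median of 1.24, with 17 of 30 higher by at least 2-fold, among them the kidney injury marker Havcr1 at 5.53. By its brightest probe Havcr1 read 0.38 in wild type sham, -4.91 in knockout sham and 0.63 in knockout injured. With normexp fitted without flagged spots its response in knockout was 3.41. A second Havcr1 probe gave a similar response of 5.46 in knockout. In wild type that probe gave 6.21, against 3.08 for the brightest probe. A larger response of Havcr1 in knockout than in wild type thus held for 1 of its 2 probes. Proximal tubule genes had a median of -0.00, with 6 higher and 4 lower by at least 2-fold. Between the sham arrays, knockout minus wild type, their median was already -0.50. There 33 of 39 members were lower, 8 of them by at least 2-fold. A low level in the knockout sham array of female pattern thus enters their response. The collagen gene Col3a1 was higher by 3.77. Erythroid genes stood at a median of -5.90, against -1.71 in wild type. Hba-a1 read 1.86 in wild type sham, 4.92 in knockout sham and -1.13 in knockout injured. In all, 755 genes were higher and 548 lower of 17031, a total of 1303. Set against the wild type sham array, a reference chosen after seeing the data, 2926 genes were 2-fold apart.

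**Figure D2:**
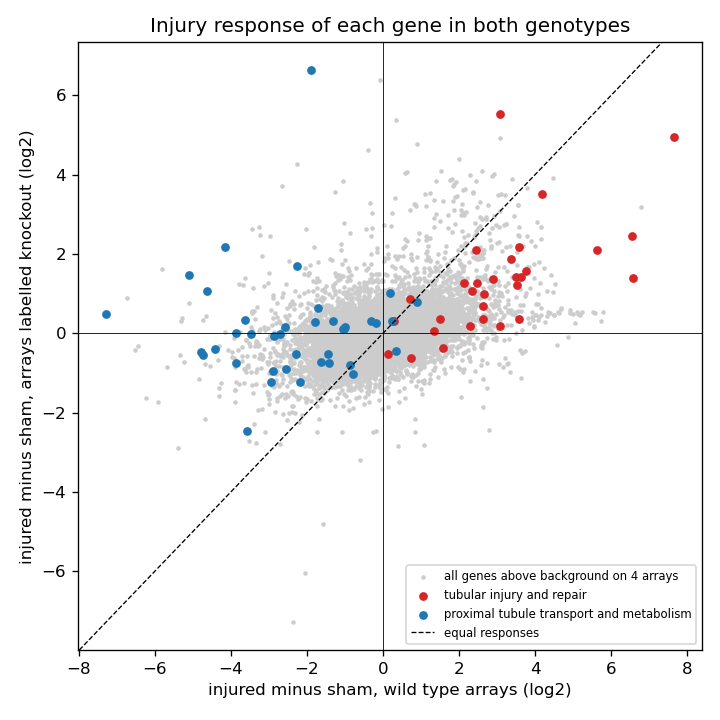
Injured minus sham (log2) in wild type on the horizontal axis and on the arrays labelled knockout on the vertical axis, 1 point per gene above background on all 4 arrays. The SD of the responses was 1.05 in wild type and 0.60 in knockout, and most tubular injury genes lay below the line of equal responses.

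Between the sham kidneys, the named genes included genes with sex-biased expression in mouse kidney and genes of fat and red cells. Acsm3 stood at -6.80 in knockout relative to wild type, and the steroid hydroxylase gene Cyp7b1 at -5.23. Acot1 was at least 1000-fold lower, as it was not above background in knockout sham. The adipocyte genes Cfd and Cidea stood at -7.10 and -6.44, and Adipoq, not above background in knockout sham, at -6.02 or further from 0. The globin genes Hba-a1 and Hba-a2 were higher by 3.06 and 3.12, the calcium sensor gene Syt10 by 4.79 and Abhd1 by 3.83. Apoh, Havcr1 and Tsen34 stood at -5.40, -5.29 and -5.28. A second Havcr1 probe stood at -2.04. Of 16982 genes, 670 were higher and 542 lower by at least 2-fold. The balance turned with quantile normalization (498 and 642), median scaling (439 and 837), the authors' value table (505 and 666), normexp fitted without flagged spots (223 and 295) and a 4-fold threshold (61 and 111).

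Interferon response genes were higher in knockout sham, with a median of 1.24 and 14 of 22 genes higher by at least 2-fold. Ifit1 stood at 1.96 and Gbp3 at 2.18, while Cxcl9 stood at -1.91. MHC class I presentation genes, which include known targets of Nlrc5, had a median of -0.22 over 15 members, with 0 of them 2-fold apart. The adipocyte median was -4.58, the erythroid median 3.12 and the urothelium median -1.57. Kidney genes higher in male mice, a list written after the sex-chromosome genes were seen, had a median of -1.47, and those higher in females a median of 0.59. With normexp fitted without flagged spots the adipocyte median was -2.75, Adipoq stood at -3.55, Havcr1 at -3.27 and Cxcl9 at -0.88.

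Between the injured kidneys, both of male pattern, tubular injury genes were lower and proximal tubule genes higher in knockout. The tubular injury median was -1.83, with 24 of 30 genes lower by at least 2-fold, among them Krt20 at -5.30 and the transcription factor gene Sox9 at -3.43. The proximal tubule median was 1.53, with 22 of 39 genes higher by at least 2-fold, among them Slc34a3 at 6.97 and the creatine synthesis gene Gatm at 4.03. Oxidative stress genes had a median of -1.01, with Hmox1 at -2.82 and Nqo1 at -2.74. The cell cycle inhibitor gene Cdkn1a stood at -2.96. Of 16732 genes, 1448 were higher and 1303 lower by at least 2-fold, a balance that turned with median scaling (1324 and 1449), the mean over probes (1289 and 1343) and normexp fitted without flagged spots (774 and 800).

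Immune and vascular genes also differed between the injured kidneys. MHC class II genes had a median of 2.49, with Cd74 at 3.55 and H2-Ab1 at 3.40. Interferon response genes had a median of 2.30, with 17 of 22 higher by at least 2-fold and Usp18, not above background in wild type injured, at 3.73 or more. Endothelial genes had a median of 1.62, with Kdr at 2.45. Macrophage genes had a median of 1.07, with C1qa at 3.28 and Chil3 at -4.21, and neutrophil genes had a median of -1.55, with S100a8 at -2.11. MHC class I presentation genes had a median of 0.20, with Psmb9 at 1.63. Among random lists matched on expression, the medians of the tubular injury and oxidative stress lists lay at percentile 0, and those of the proximal tubule, interferon, MHC class II, endothelial and macrophage lists at percentile 100. Many other lists were also extreme, with cell cycle at 100, immediate early and hypoxia at 0, and podocyte at 99.99, while MHC class I lay at 84.7. The percentiles thus do not single out the lists named. Random lists draw genes independently, while members of a list can vary together. The wild type injured array had the lowest signal of the 4. With normexp fitted without flagged spots the medians were 1.11 for interferon, 1.62 for MHC class II and 0.39 for macrophage genes, with Usp18 at 1.14 and C1qa at 1.09.

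**Figure D3:**
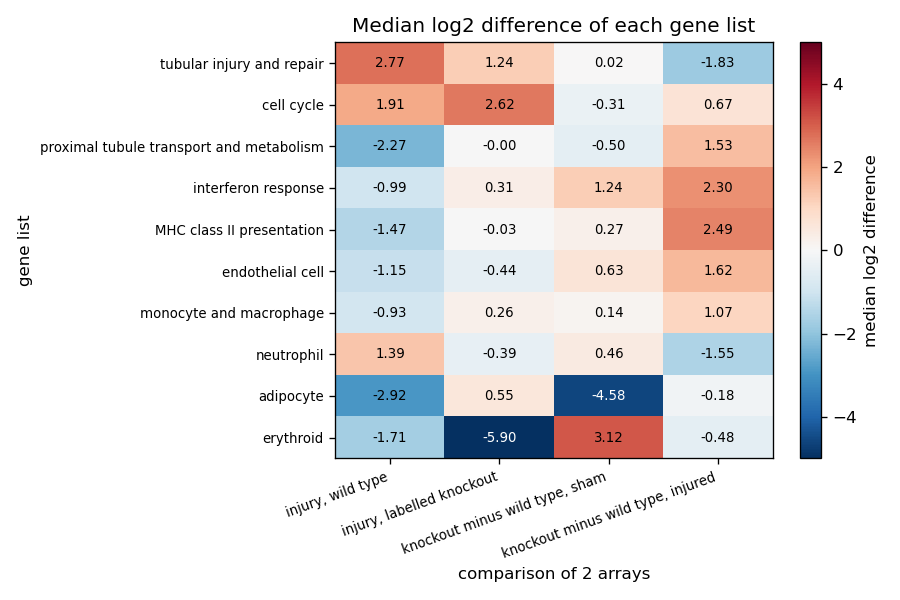
Median log2 difference of 10 gene lists (vertical axis) in 4 comparisons of 2 arrays (horizontal axis), printed in each cell. Tubular injury genes stood at 2.77 after injury in wild type, 1.24 in knockout, and -1.83 between the injured arrays.

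Over both treatments, Syt10 was higher on the arrays labelled knockout by 4.79 in sham and 7.53 in injured kidneys. The transcription factor gene Sox14 was higher by 2.89 and 2.75. The centrosomal gene Cep85 stood at -3.30 and -3.99. Nlrc4, an inflammasome receptor gene, was not above background on either array labelled knockout, at least 2.94 and 3.76 below wild type. With normexp fitted without flagged spots Sox14 stood at 1.20 and 0.53, Cep85 at -1.17 and -1.98 and Nlrc4 at -0.94 and -1.65. By size, 196 genes were higher and 93 lower by at least 2-fold in both treatments. These counts too used each probe's own signal and not the bounds. Tsix, among the higher genes, stood at 0.93 between injured kidneys as a bound.

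Of 16555 genes tested by limma for genotype, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.769. At an unadjusted p under 0.05, 566 genes were higher and 347 lower, and with normexp fitted without flagged spots limma called 127. Interferon response genes had a median of 1.71 over 22 members, of which 13 were higher adjusted over the list alone, against 0 over all genes. Endothelial genes had a median of 1.07 and tubular injury genes -0.97. Markers of fat and sex moved in the same comparison, with medians of -2.24 over 4 adipocyte genes (camera adjusted p = 0.0147) and -3.41 over 4 sex-chromosome genes (camera adjusted p = 0.0193). The camera adjusted p was 1.27e-13 for interferon, 6.00e-07 for endothelial and 3.46e-07 for tubular injury genes at the preset correlation, and 0.871 for each of these 5 lists with an estimated correlation.

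The injury response was smaller on the arrays labelled knockout over 14949 genes above background on all 4 arrays. The SD of the response was 1.05 in wild type and 0.60 in knockout, a ratio of 0.572. Cell cycle genes ran the other way, with medians of 1.91 in wild type and 2.62 in knockout, and a median response difference of 0.91 (0.30 with normexp fitted without flagged spots). Between the sham arrays, knockout minus wild type, their median was already -0.31, with 23 of 26 members lower. Between the injured arrays it was 0.67, and -0.05 with normexp fitted without flagged spots. Of 1965 genes higher by at least 2-fold in wild type, 327 were also higher by at least 2-fold in knockout, and of 1852 lower in wild type, 214 were also lower. The responses of 1441 genes were at least 2-fold greater in knockout and those of 1413 at least 2-fold smaller, counted with sign. Slc34a3 differed by 7.77 and Acsm3 by 8.52. Acsm3, a member of the male-higher list, read 4.33 in wild type sham and -2.47 in knockout sham. It read 2.45 in wild type injured and 4.17 in knockout injured, so its value rests on the sham array of female pattern. The growth factor gene Fgf2 differed by -5.26 (-3.36 with normexp fitted without flagged spots) and the arginase gene Arg2 by -4.96. Across genes, which are not independent replicates, the responses correlated with a Pearson r of 0.459 and a Spearman rho of 0.501.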

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

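In this part, the tests of the sex of the knockout sham animal as the source of the smaller response, of the signal scale of the knockout slide and of exchanged labels were chosen after at least part of the result had been seen. The other tests were written before they were run. Among these, the tests of sex and of fat in the sham kidneys used lists written after the sex-chromosome genes or the first fat genes had been seen.

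Among the genes named by the fixed rule, list members included, 26 responded to injury in opposite directions in the 2 genotypes, each by at least 2-fold. With 1 array per group these differences were not tested. The response in knockout minus that in wild type was 8.52 for Acsm3, 6.51 for Cyp7b1, 6.37 for Apoh, 4.82 for Azgp1, 6.57 for Slc7a13, 6.33 for Slc22a30, 5.70 for Cyp2e1, 3.97 for Cyp4b1, 3.18 for Ces1f and 7.43 for Igh-VJ558. The 6 probes of Igh-VJ558 above background did not all share this: they ranged from -5.82 to 0.48 in wild type and from -0.15 to 1.61 in knockout. It was 3.63 for C4b, 2.88 for Ccl5, 2.51 for Ciita, 3.80 for Itgax, 3.69 for Retn and 3.43 for Thy1. With normexp fitted without flagged spots it was 0.89 for C4b, 1.34 for Ciita, 1.01 for Itgax and 2.32 for Retn. It was -5.24 for Abcc3, -4.49 for Klk1b27, -3.66 for Retnlg, -2.45 for S100a8 and -2.55 for S100a9. With 1 array of a pair not above background, it was at least 3.08 for Ccl12, 4.37 for Cxcl9, 5.50 for Jchain and 6.05 for Pzp, and -6.73 or further from 0 for Septin1. The knockout response uses the sham array with the female pattern. Between the injured arrays, knockout minus wild type, some of these genes were less than 2-fold apart. Azgp1 stood at -0.06, Pzp at -0.20 and Cyp4b1 at -0.42 there. Others were further apart, with Slc22a30 at 3.57 and Slc7a13 at 3.25.

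The 2-fold differences between the sham kidneys covered 1212 genes. Slide and genotype are the same split, and of the 858 such genes above background on all arrays, 55.7% differed the same way between the injured arrays on the same slides. A difference carried over from sham would have given 96.5%, which argues against a fixed effect of the slide, and equally of genotype, as the source of most of them. Sex may account for part: the male-higher kidney genes had a median of -1.47 between the sham arrays, although they stood at 1.05 between the injured arrays of like sex, and they cover few of the genes. Fat in the wild type sham sample stays open, since further fat markers were higher there by medians of 0.66 to 2.15 against the other arrays, between the bounds set beforehand. Kidney expresses some of these markers, while Adipoq and Plin1 were above background in wild type sham alone. Cidec, of the first adipocyte list, was not highest there, at 1.73 against 1.87 in wild type injured.

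The smaller injury response on the arrays labelled knockout was weighed against 3 technical explanations. Low signal of the wild type injured array, where it acts on genes near background, would leave the brightest genes alike. Among the brightest of 4 equal groups the ratio of response SDs was 0.501. This ratio cannot address a fault of that sample or array that also reached bright genes. The sex of the knockout sham animal cannot enter the comparison of the injured arrays, where tubular injury genes had a median of -1.83, and with the male wild type sham array as the reference the ratio over all genes was 0.742 and the count 2926 against 1303, which argues against sex as the whole cause and leaves a part open. A compressed scale on the knockout slide would need control transcripts with flatter slopes, and the ratio of slopes was 0.956 against 0.572 for the responses. Genotype, a difference in the severity of injury between 2 single animals, and such a fault of the wild type injured sample or array stay open. Each may be the cause, and they were not tested.

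Nlrc5 itself differed by at most 0.32 between genotypes within a treatment, and by -0.66 in injured kidneys with normexp fitted without flagged spots. Exchanged labels were predicted to lower the signal by at least 1 on both arrays labelled wild type, and neither array showed that. A probe outside the deleted part would show no difference whichever way the arrays were labelled. As the position of this 1 probe relative to the deletion is unknown, the test cannot decide whether labels were exchanged.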

How the results depend on the processing

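The 2 refits below that change the reference array or the normexp fit, and the one leaving out sex-biased, fat and red cell genes, were chosen after seeing the data. Counts follow the order sham genotypes, injured genotypes, injury in wild type, injury in knockout, response difference, for those that moved by over 1.5 times. The planned normexp correction gave 4426 limma calls for injury and 101 for genotype, and 516 and 1430 genes between genotypes and 5574 for injury in knockout. Its fit failed on the knockout injured array, where extreme spots (lowest signal minus local background -11068.73) pulled the fitted background to -225.2, against -5.39 to -1.30 elsewhere. Refitted without flagged spots (fitted background -0.31), normexp gave 730 and 127 limma calls, and 518, 1574, 602 and 1889 genes for sham, injured, injury in knockout and response difference. The cause of the remaining difference was not tested. With no filter the counts were 2262 (sham), 2135 (injury in knockout) and 5280 (response difference), since more genes enter. At 1.5-fold they were 3949, 5912, 8020, 3782 and 5835, and at 4-fold 172, 629, 1204, 274 and 688. The knockout injury count against wild type sham was 2926. Leaving out 1 array gave 0 to 702 limma calls for injury, the highest without the knockout injured array, and 0 for genotype. These fits also leave out the other factor, since 3 arrays carry no residual degree of freedom with it, and assume that the lone array varies like the others. On all 4 arrays, leaving it out gave 0 calls for both. Without sex-biased, fat and red cell genes each count stayed within 1.5 times. The share of higher calls between sham kidneys was 55.3%, and 34.4% with median scaling. For the response difference the balance turned with no filter (2311 higher, 2969 lower), the mean over probes (1301 and 1433) and 1.5-fold (2859 and 2976), and for injury in knockout at 1.5-fold (1834 and 1948). Median scaling put the median of all genes at -0.11 between sham kidneys, against 0.05. In the failed normexp run, the sign turned for Cfd (0.62) between injured kidneys, for Cfd (1.05), Cox8b (0.047), Itm2a (0.63), Ndrg4 (0.57) and Tmprss6 (0.90) after injury in knockout, and for the neutrophil median between injured kidneys (0.50). In the refit, Gpr142 turned to -0.22 between injured kidneys. With the mean over probes Tbx18 stood at -0.0043 after injury in knockout, and with no filter the dendritic cell median stood at -0.056 between injured kidneys. The cause of these last 3 was not tested. Of 1483 alternatives over 193 gene values, 472 moved by more than the spot noise, 8 turned and 1003 did neither, and of 1428 over 179 list medians 309 moved and 2 turned, where a turn counts for values of at least 2-fold. Response differences given as bounds were not rerun. The normexp refit, whose offset of 50 draws in differences of dim genes, moved 72 gene values and 40 list medians of 0.5 or more by over 1.5 times and turned 8 of the medians. No paired analysis was possible because each group has 1 array. The slide was not run as a block, being the same split as genotype. Signal near background limits dim genes, most on the wild type injured array, where 67.2% of probes were well above background.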

Other observations

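Complement and acute phase genes were also measured after injury. Fgb was higher by 3.11 in wild type and 3.50 in knockout and Saa2 by 3.23 (1.62 with normexp fitted without flagged spots, an alternative chosen after seeing the data) and 2.75, while the median of the list was 0.22 and 0.49. Fibroblast and matrix genes had medians of 0.57 (0.29 with the same alternative) and 0.88, although Dcn stood at -2.88 in wild type and Lum, not above background in its injured kidney, at -3.23 or further from 0 (-0.76 with the same alternative). Hypoxia and glycolysis genes had a median of -0.68 between the injured arrays, with Hk2 at -2.38, and a median of -0.45 with the same alternative. The thick ascending limb gene Egf stood at -6.25 after injury in wild type and at -1.62 in knockout.

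A chromosome segment carried along with a targeted allele was a hypothesis written before its test. It would show as genotype differences in the genes within 2 Mb of Nlrc5. The mean absolute genotype effect of 52 such genes was 0.435, at percentile 77.5 of random lists matched on expression. This lay below the 95th percentile that had been set, which argues against large differences over the whole segment. A mean does not address single genes. Between the sham arrays 2 of 55 neighbours were higher and 6 lower by at least 2-fold, with Ces1g at -2.62 and Ces1f at -2.49. Over all genes 1212 of 16982 were 2-fold apart there, in a comparison that also compares sexes. The median response difference of 49 neighbours was 0.23, at percentile 98.1.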
